A study of Oryza sativa Indica Group with 6 samples.

How the data were processed

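Small RNA sequencing libraries from mature rice panicles before anthesis (stage 12) of the Indica cultivar Pusa Basmati 1 were compared in 3 groups of 2 libraries each: wild type (WT), AGO17 over-expression (OE) and AGO17 knock-down (KD). Per the labels, total RNA was extracted with Trizol and size-fractionated before library preparation. AGO17 mRNA is not measured by such libraries, so the dose of AGO17 in each group rests on the labels. Each deposited file holds distinct sequences of 16 to 35 nt and their raw read count in 1 library. The aligner, the adapter trimming and any removal of structural RNA are not given in the sources used here.

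The libraries held 12815588 and 12052721 reads (WT), 8678629 and 11670457 reads (OE) and 9414628 and 9257054 reads (KD). Reads of 18 to 30 nt were analysed, which made up 93.1 ± 0.271% (WT), 92.9 ± 1.76% (OE) and 83.3 ± 0.189% (KD) of the reads (mean ± SD, n = 2, as throughout). At a floor of 3 reads per library, abundances down to between 0.252 and 0.390 RPM could be told from 0. Sequences seen once made up 80.2% (WT), 80.1% (OE) and 83.3% (KD) of the distinct sequences and 35.1%, 34.1% and 39.1% of the reads. Floors and counting intervals cover counting error only.

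Reads were counted by length (13 classes), by the first base and length (20 classes of 20 to 24 nt, named by base and length, with T for uridine) and by distinct sequence. Families of miRNAs were counted from reads of 20 to 24 nt that held positions 3 to 18 of a listed mature sequence without mismatch, within 2 nt of their usual place. miR2118, miR2275 and tasiR-ARF were counted instead by a shared sequence pattern (ATGCC[TA]C[CT]CAT[TG]CC, TT[CT]CTCCAATATCT and TTGACCTTG.AAGAC, a point for any base) within 2 nt of its usual place. Of 38 families listed from general knowledge, 34 with at least 10 reads in at least 2 libraries were tested. The other 4 were below that minimum and not analysed further, namely miR1850 and, with a count of 0 here, miR171, miR1320 and miR1861. Abundances are counts scaled to RPM over the reads of 18 to 30 nt (written rpm).

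All tests used the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with all 6 libraries in one fit, which leaves 3 residual degrees of freedom, and Benjamini-Hochberg adjustment over the features of each comparison at a threshold of 0.05. The edgeR p-values rest on more than these 3 degrees of freedom, because the estimate of spread is shared across features. Single sequences were filtered with filterByExpr (96010 kept) and scaled by TMM. The same factors (1.03 and 1.03 in WT, 1.09 and 1.13 in OE, 0.861 and 0.890 in KD) were used for the families, and no TMM for the length and first-base classes. Sets were tested with camera (limma 3.58.1) at a preset correlation of 0.01 over 26 sets, namely the 20 first-base classes, conserved miRNAs, monocot miRNAs, copper miRNAs (miR397, miR398, miR408, miR528), nutrient miRNAs (miR395, miR399, miR827), the phasiRNA triggers miR2118 and miR2275, and miR390 with tasiR-ARF. At the preset correlation the set tests treat sequences, not libraries, as the replicates, so their p-values do not measure the spread between libraries. DESeq2 1.42.0 served as the other tool. Counting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawing used matplotlib 3.10.9.

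The comparisons, the families, the tests and the rule for naming were set before the data were examined. Families past the threshold are named by size of change, up to 15 per comparison, together with miR168, miR162, miR2118, miR2275, miR390, tasiR-ARF, miR397 and miR528 whatever their test. Single sequences are named as the 5 with the largest change per comparison and direction, among those past the threshold with at least 50 rpm in a group and no overlap between the groups, with overlapping sequences (18 nt or more) counted as one. Pieces of U6, 5S and 5.8S RNA were counted by exact match to plant sequences written down after the KD results had been seen. Reads outside 18 to 30 nt entered no test.

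Nothing says that the replicates came from separate plants, so the p-values measure only the spread between these samples. That spread may be technical, and it is in part pooled over features and not each feature's own. The replicate numbers did not pair the libraries (correlations of the deviations −0.057, −0.029 and 0.168), so the main tests used no block, which was fitted only as an alternative. Tested on simulated changes added to the OE against WT comparison, the methods recovered 7 of 100 sequences changed 2-fold and 62 of 100 changed 4-fold, with 4 unchanged sequences called. They recovered 10 of 10 families (1 unchanged family called), 1 of 2 lengths, 3 of 3 first-base classes and 1 of 1 set.

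Alternatives were library totals without TMM, TMM from the families alone, DESeq2, other minimum counts, distinct sequences in place of reads, leaving out sequences seen once or the 20 most abundant, exact mature sequences, a replicate block, only the 2 groups compared, an estimated correlation in the sets, and leaving out each library in turn. After the data had been seen, TMM from 20 to 24 nt, family reads of 18 to 26 nt, miR397 in any register and a split of the WT libraries for the overlap were added, and the lengths, classes and families followed through the alternatives were narrowed to those named here. Counts in genome windows and matches to the AGO17 gene were planned but not run, since no genome sequence was used here.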

Results

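The KD libraries stood apart from the other 4. Across the 96010 sequences tested, log2 abundances correlated at 0.94 between the WT libraries, 0.91 between the OE libraries and 0.89 between the KD libraries. WT and OE libraries correlated at 0.78 to 0.80 and KD libraries correlated with the others at 0.43 to 0.48. In a multidimensional scaling of the 6 libraries, dimension 1 (61.2%) parted KD from the rest and dimension 2 (26.8%) parted OE from WT.

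In OE, families that trigger or guide secondary siRNA production were lower than in WT, within a general fall (median −0.77 over the 34 families tested). miR2118, which triggers 21-nt reproductive phasiRNAs, fell from 105 ± 3.35 rpm to 34.9 ± 1.94 rpm (log2 fold change −1.70 ± 0.30 SE, adjusted p = 6.8e-06). miR2275, the trigger of 24-nt phasiRNAs, fell from 51.2 ± 6.42 to 19.2 ± 5.44 rpm (−1.52 ± 0.31, adjusted p = 4.3e-05), a call that ended with TMM from the families alone (−0.77, adjusted p = 0.20). miR390, which starts tasiRNA production from TAS3, fell from 26.9 ± 2.43 to 13.4 ± 2.73 rpm (−1.12) and tasiR-ARF, its product against auxin response factors, from 7.72 ± 0.604 to 4.29 ± 0.151 rpm (−0.96, adjusted p = 0.025). The calls of miR390 and tasiR-ARF ended without WT replicate 1 (adjusted p = 0.062 and 0.26) and without WT replicate 2 (0.11 and 0.15).

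Of 4 copper-related families, 2 were lower in OE. miR528, which targets ascorbate oxidase and other copper proteins, fell from 4.81 ± 0.50 to 0.975 ± 0.221 rpm (−2.42 ± 0.51, adjusted p = 8.8e-05), and miR408, against plantacyanin-type proteins, from 17 ± 0.0781 to 6.41 ± 1.60 rpm (−1.53 ± 0.33, adjusted p = 9.9e-05). Families against auxin response factors (miR160, −1.31), NAC factors (miR164, −1.24), APETALA2-like factors (miR172, −1.28), MADS-box factors (miR444, −1.09), the F-box protein LCR (miR394, −1.12) and DCL1 (miR162, −0.999 ± 0.30, adjusted p = 0.0040) fell as well. Of the nutrient families, miR827 (−1.19) fell, as did miR395 (−3.04 ± 1.16), which rested on 11 and 10 reads in WT against 2 and 0 in OE (−6.16 without OE replicate 1 and −1.87 without OE replicate 2), whereas miR399, which targets PHO2, rose from 14.3 ± 0.0918 to 25.4 ± 5.83 rpm (0.72, adjusted p = 0.042). miR168, which targets AGO1, was 1171 ± 18.9 in WT and 1619 ± 236 rpm in OE (0.36, adjusted p = 0.27, and 1.05 with adjusted p = 1.8e-04 under TMM from the families alone). For miR397, a copper family, the main count held only 20 and 21 reads in WT and 10 and 10 in OE (−0.84, adjusted p = 0.23). Counted in any register, a choice made after the data were seen, it was called higher in OE (92.1 ± 13.7 against 35.6 ± 1.26 rpm in WT, 1.27, adjusted p = 1.9e-04).

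By the edgeR quasi-likelihood test, 17 of 34 families passed in OE against WT, 1 higher and 16 lower. The scaling by TMM moved all OE values by −0.11 log2 against library totals, which gave 4 higher and 16 lower, whereas TMM from the families alone gave 12 higher and 9 lower. Under the latter miR162 (adjusted p = 0.15), miR395 (0.088), miR172 (0.050) and tasiR-ARF (0.40) did not pass, and with a replicate block miR395 did not (0.055). The count was 6 without WT replicate 1 and 4 without WT replicate 2. Without WT replicate 1 the calls of miR395, miR172, miR827, miR394 and miR444 ended (adjusted p = 0.062 each), as did miR162 (0.11) and miR399 (0.33). Without WT replicate 2 the same 7 ended (0.075, 0.11, 0.098, 0.098, 0.098, 0.098 and 0.32) together with miR160 (0.066) and miR164 (0.11). The call of miR399 also ended without OE replicate 1 (0.16) and that of miR395 without OE replicate 2 (0.12). With family reads of 18 to 26 nt tasiR-ARF (0.086) and miR399 (0.058) did not pass. Of the 15 families named by size, miR2118, miR408 and miR528 kept their call in every alternative run, with smaller values (−0.99, −0.84 and −1.72) under TMM from the families alone.

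The set tests placed the phasiRNA triggers lowest in OE. The 15 sequences of miR2118 and miR2275 had a median log2 fold change of −1.63 (adjusted p = 2.0e-09 at the preset correlation, 0.16 with an estimated correlation), and both families were lower. Copper miRNAs had a median of −1.29 (adjusted p = 7.3e-04, 0.35 with an estimated correlation and 0.22 with a minimum of 10 rpm; 2 of 4 families lower), and miR390 with tasiR-ARF a median of −1.03 (adjusted p = 0.020, 0.35 with an estimated correlation and 0.23 with the minimum of 10 rpm; 2 of 2 lower), with adjusted p = 0.051 without WT replicate 1. Conserved families (1 higher and 10 lower of 21, or 2 and 10 when adjusted over the list alone) and monocot families (3 lower of 10, or 2 over the list alone) did not pass as sets (adjusted p = 0.10 and 0.72), although the conserved set passed without OE replicate 1 (0.0019) and with the minimum of 10 rpm (0.035). Nutrient miRNAs (1 higher and 2 lower of 3) did not pass (adjusted p = 0.81), with a median of −0.76 and a mean of 0.00. For these lists other than the conserved and monocot ones, the counts over the list alone were the same. The estimated correlations were −0.068 for the phasiRNA triggers, 0.014 for the copper miRNAs and −0.092 for miR390 with tasiR-ARF. With the preset at 0.01, correlation between sequences does not account for the lost calls of these sets.

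**Figure D1:**
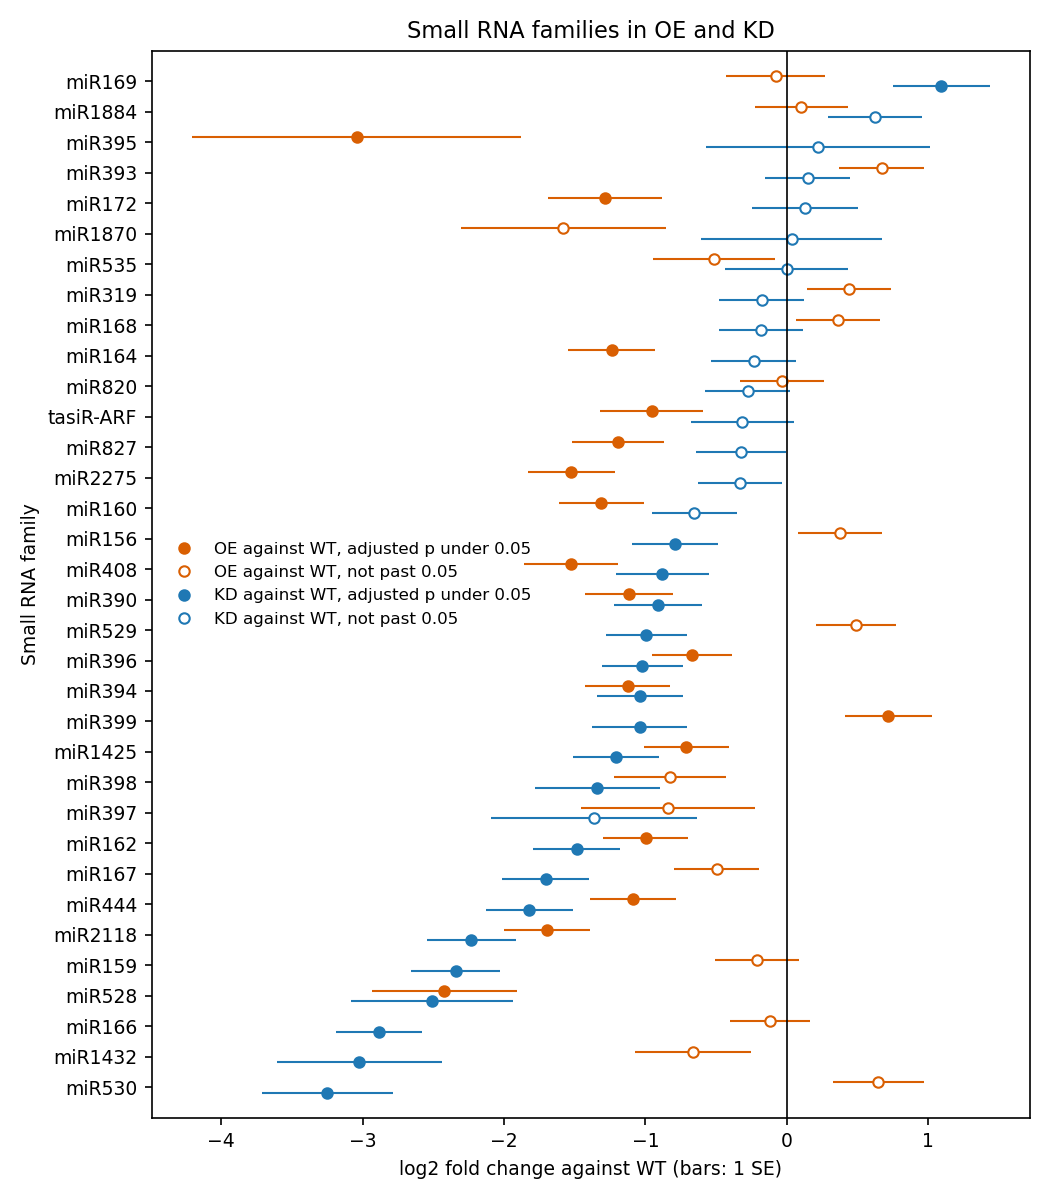
Log2 fold changes of 34 small RNA families in OE and in KD against WT, with TMM from all tested sequences (bars, 1 SE; 2 libraries per group). Of the families named in the text, miR399, miR394, miR396, miR168, miR2275, miR390 and tasiR-ARF change sign in KD under TMM from the families alone.

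No length class in OE passed against WT. Reads of 24 nt, the usual size of heterochromatic siRNAs, made up 47.5 ± 0.298% in WT and 45.7 ± 3.16% in OE, and reads of 21 nt, the size of most miRNAs and of 21-nt phasiRNAs, 14.6 ± 0.355% and 14.0 ± 2.5%. Reads of 22 nt made up 6.13 ± 0.0881% and 6.21 ± 0.470%, and reads of 23 nt 13.7 ± 0.106% and 13.8 ± 0.0672%. Reads of 18 nt (2.39 ± 0.0852% and 3.33 ± 1.29%) and of 19 nt (2.47 ± 0.0752% and 3.14 ± 0.954%) were more frequent in OE by the mean, mainly in OE replicate 1 (for 18 nt, 4.24% against 2.42% in OE replicate 2). By the edgeR quasi-likelihood test 0 of 13 lengths passed (0 at an unadjusted p under 0.05, and 0 by DESeq2). Of the 20 first-base classes 0 passed, with 2 at an unadjusted p under 0.05 and 1 by DESeq2. These were G22 (0.33, adjusted p = 0.27, the class DESeq2 called) and T22 (−0.19, adjusted p = 0.38). As sets of single sequences at the preset correlation, 8 of the classes passed in OE, led by T21 (median −0.43, adjusted p = 6.4e-06), C21 (−0.35, adjusted p = 7.3e-04) and A20 (0.31, adjusted p = 9.2e-04), and 0 passed with an estimated correlation.

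Single sequences in OE included 24-nt species that were rare in WT. Several of the 10 sequences named here moved the same way in KD by their means. Of those higher in OE, the 18-nt sequence was at 44.2 rpm in KD. The 24-nt ones at 176 and 159 rpm in OE were at 54.9 and 33.8 rpm in KD. Those at 60.6 and 53.7 rpm in OE were at 1.34 and 4.76 rpm in KD. The sequences that fell to 13.6, 13.4 and 27.6 rpm in OE were at 7.96, 32.1 and 47.7 rpm in KD. CACTTGCACTGTGGAGAACTCAAA rose from 0.514 ± 0.224 to 60.6 ± 2.67 rpm, CCCGAGACGTAACTCTAATGCTAT from 8.24 ± 1.43 to 176 ± 3.16 rpm, GTTACGAGATGTAGAAGTTGAATT from 11.5 ± 0.513 to 159 ± 14.2 rpm and GAAACGGGACTTGAATTGTAGGCC from 4.20 ± 0.231 to 53.7 ± 1.93 rpm. The 18-nt AGACCGGTAGACTTGAAC rose from 0.487 ± 0.570 to 69.1 ± 28.8 rpm. ATGCACCCGGATACTGTAGAACAC fell from 98.0 ± 5.25 to 0.154 ± 0.0398 rpm, with 2265 reads in WT and 3 in OE (WT over OE 618, 95% counting interval 211 to 2999), and ATGCACCCGGATACTGTAGATCAC from 65.5 ± 2.72 to 1.74 ± 0.502 rpm. ATATACGTACTTGGCTCGGCC, TCTGAATTCCGCCAGTGCCCGAAA and AAGAGTACACTATCGGAAGACGCC fell to 13.6 ± 4.35, 13.4 ± 0.474 and 27.6 ± 0.579 rpm from 72.1 ± 3.35, 57.8 ± 2.22 and 113 ± 7.76 rpm. The largest adjusted p among these 10 sequences was 1.2e-06 (ATATACGTACTTGGCTCGGCC).

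In OE against WT, 13780 of 96010 sequences passed by the edgeR quasi-likelihood test, 6633 higher and 7147 lower (48.1% higher, and 59.8% with library totals), and 3176 by DESeq2. Among 21-nt sequences, 567 rose and 1765 fell. The count of 13780 was 3216 without WT replicate 1, 3626 without WT replicate 2 and 9046 without OE replicate 2.

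**Figure D2:**
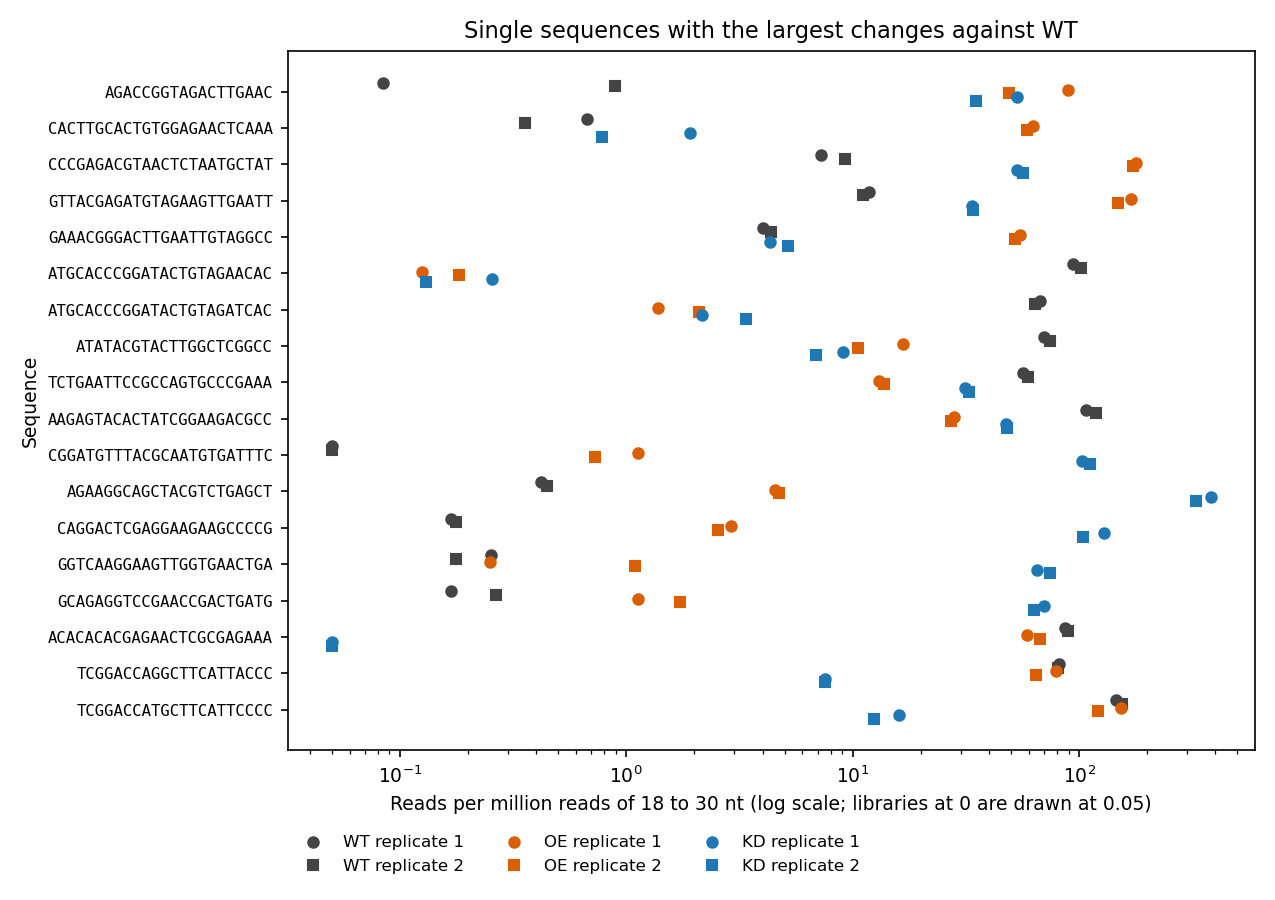
Abundance of the named single sequences in each of the 6 libraries, in rpm on a log scale; libraries at 0 are drawn at 0.05.

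In KD, several of the most abundant miRNAs of the panicle were much lower than in WT. miR166, which targets class III HD-ZIP factors, fell from 19670.0 ± 499 to 2265 ± 233 rpm (−2.88 ± 0.30, adjusted p = 3.0e-14). miR159, against GAMYB factors, fell from 1039.7 ± 117 to 174 ± 48.9 rpm (−2.34), miR167, against auxin response factors, from 416 ± 18.4 to 108 ± 17.8 rpm (−1.71) and miR444, against MADS-box factors, from 253 ± 7.68 to 60.8 ± 11.6 rpm (−1.82). Of the scarcer families, miR530 fell from 9.46 ± 0.167 to 0.836 ± 0.0791 rpm (−3.25 ± 0.46, adjusted p = 2.2e-09), miR1432 from 5.02 ± 0.448 to 0.513 ± 0.175 rpm (−3.02) and miR528 from 4.81 ± 0.50 to 0.708 ± 0.101 rpm (−2.51). miR2118 fell to 19 ± 2.28 rpm (−2.23 ± 0.32, adjusted p = 2.1e-09). These 8 families kept their call in every alternative run, but under TMM from the families alone the values were smaller (miR166 −1.74, miR159 −1.22, miR167 −0.57, miR444 −0.69, miR530 −2.12, miR1432 −1.90, miR528 −1.38 and miR2118 −1.09).

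Other families were lower in KD, but not in every alternative. miR162, which targets DCL1, fell to 65.6 ± 11.6 rpm (−1.49), and miR1425, against Rf1-like proteins, from 481 ± 20.8 to 176 ± 20.1 rpm (−1.21), and with TMM from the families alone neither passed (adjusted p = 0.098 and 0.27). miR396, against growth-regulating factors, fell from 15571 ± 155 to 6509 ± 893 rpm (−1.02), but with TMM from the families alone it was called higher (0.12, adjusted p = 0.013), as miR399 (−1.04), miR394 (−1.04) and miR390 (−0.91) turned to 0.10, 0.09 and 0.22, short of the threshold. miR398 (−1.34) lost its call under that scaling (−0.22, adjusted p = 0.64), and its value was −2.25 without KD replicate 1 and −0.78 without KD replicate 2. The calls of miR396, miR399, miR394, miR390 and miR398 ended without WT replicate 1 (adjusted p = 0.078, 0.11, 0.081, 0.11 and 0.13), without WT replicate 2 (0.085, 0.12, 0.10, 0.20 and 0.054) and without KD replicate 2 (0.092, 0.087, 0.098, 0.18 and 0.23). miR169, against NF-YA factors, rose from 5.96 ± 0.248 to 10.8 ± 2.21 rpm (1.09, adjusted p = 0.0046), a call that ended without WT replicate 1, WT replicate 2 or KD replicate 1 (adjusted p = 0.11, 0.14 and 0.085). miR168 (−0.18), miR2275 (−0.33), tasiR-ARF (−0.32) and miR397 (−1.36, adjusted p = 0.0998 from 2 and 7 KD reads; −0.75 without KD replicate 1 and −2.49 without KD replicate 2) did not pass, and the signs of miR168, miR2275 and tasiR-ARF turned with TMM from the families alone (0.96, 0.85 and 0.83; adjusted p = 2.4e-04, 0.14 and 0.024). miR397 did pass with library totals (adjusted p = 0.045), with only the 2 groups compared (0.029), with family reads of 18 to 26 nt (0.031) and in any register (12.6 ± 0.549 rpm in KD, −1.26, adjusted p = 2.8e-04).

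In KD against WT, 19 of 34 families passed by the edgeR quasi-likelihood test, 1 higher and 18 lower. TMM moved all KD values by 0.23 log2 against library totals, which gave 1 higher and 20 lower, whereas TMM from the families alone gave 14 higher and 8 lower. The count of 19 was 10 without WT replicate 1 or WT replicate 2 and 11 without KD replicate 2. As sets, conserved miRNAs (1 higher and 11 lower of 21) had a median of −1.07 (adjusted p = 1.9e-12, and 0.43 with an estimated correlation), monocot miRNAs (6 lower of 10) −0.65 (adjusted p = 0.0023, and 0.55 with an estimated correlation) and copper miRNAs (3 lower of 4) −1.61 (adjusted p = 0.0034, and 0.24 with an estimated correlation). The phasiRNA triggers (1 lower of 2) had a median of −2.05 (adjusted p = 3.0e-05, and 0.097 with an estimated correlation). With the minimum of 10 rpm the copper set was −0.70 (adjusted p = 0.54), and neither the monocot set nor the phasiRNA triggers passed (adjusted p = 0.093 each). Nutrient miRNAs (1 lower of 3, adjusted p = 0.13) and miR390 with tasiR-ARF (1 lower of 2, adjusted p = 0.19) did not pass, and adjusting over each list alone gave the same counts.

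KD libraries held more 23-nt and fewer 21-nt reads. Reads of 23 nt rose from 13.7 ± 0.106% to 21.5 ± 0.0126% (0.66 ± 0.04, adjusted p = 0.00015), and reads of 21 nt fell from 14.6 ± 0.355% to 8.93 ± 1.12% (−0.71 ± 0.15, adjusted p = 0.037). The fall at 21 nt did not pass without WT replicate 1 (adjusted p = 0.19), WT replicate 2 (0.23) or KD replicate 2 (0.073), without the 20 most abundant sequences (−0.50, adjusted p = 0.092) or with distinct sequences in place of reads (−0.22, adjusted p = 0.29). Reads of 24 nt were 47.5 ± 0.298% in WT and 40.7 ± 2.18% in KD (−0.22 ± 0.06, adjusted p = 0.062), a fall that passed by DESeq2 (0.0049), with distinct sequences (0.0094), without the 20 most abundant sequences (0.024), with a replicate block (0.023) and with only the 2 groups compared (0.0040). In all, 2 of 13 lengths passed.

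The added 23-nt reads in KD began mainly with G, C and A, and the lost 21-nt reads with U. Class G23 rose from 2.16 ± 0.0206% to 4.83 ± 0.00643% (1.16 ± 0.02, adjusted p = 2.2e-06), C23 from 2.91 ± 0.0428% to 5.98 ± 0.0119% (1.04 ± 0.02, adjusted p = 2.2e-06) and A23 from 4.32 ± 0.0478% to 6.09 ± 0.0218% (0.50). Class T21, the usual form of miRNAs bound by AGO1-type proteins, fell from 7.94 ± 0.134% to 3.36 ± 0.414% (−1.24 ± 0.15, adjusted p = 0.0031), and T22 fell by 0.49. A24, the usual form of siRNAs bound by AGO4-type proteins, fell from 22.3 ± 0.0978% to 16.2 ± 0.934% (−0.46 ± 0.08, adjusted p = 0.0072), with adjusted p = 0.061 without WT replicate 1 and 0.058 without WT replicate 2. In all, 11 of 20 classes passed, 8 higher and 3 lower, the others higher being G20 (1.21), C22 (0.82), A22 (0.61), G22 (0.60) and T23 (0.12). G20 did not pass without WT replicate 1, WT replicate 2 or KD replicate 1 (adjusted p = 0.12, 0.11 and 0.078), G22 did not without sequences seen once (0.22, adjusted p = 0.095), and T23 did not without the 20 most abundant sequences (adjusted p = 0.071) or with distinct sequences (−0.016, adjusted p = 0.45). As sets of single sequences, G23 and C23 were the 2 of 26 that passed with an estimated correlation (adjusted p = 0.037 each), against 18 at the preset correlation.

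Other properties of the RNA moved with KD. Reads of 31 to 35 nt made up 1.65 ± 0.444% of all reads in WT, 1.33 ± 1.004% in OE and 7.94 ± 3.77% in KD, and reads of 16 and 17 nt 5.26 ± 0.174%, 5.73 ± 2.76% and 8.79 ± 3.58%. Pieces of U6 RNA came to 144 ± 6.71 rpm in WT, 139 ± 20 rpm in OE and 719.8 ± 25 rpm in KD, and pieces of 5.8S rRNA to 381 ± 9.32, 263 ± 13.5 and 890.5 ± 144 rpm. Exact pieces of 5S rRNA were at 0 in all 6 libraries, although reads with an added or changed base were present, so these levels show only what the files retained. The 20 sequences most abundant over all 6 libraries held 7.77% and 7.81% of the reads in WT. They held 8.59% and 8.03% in OE and 2.87% and 2.47% in KD. The list was ranked by reads summed over the libraries, most of them WT and OE. A lower share in KD follows in part from that ranking.

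**Figure D3:**
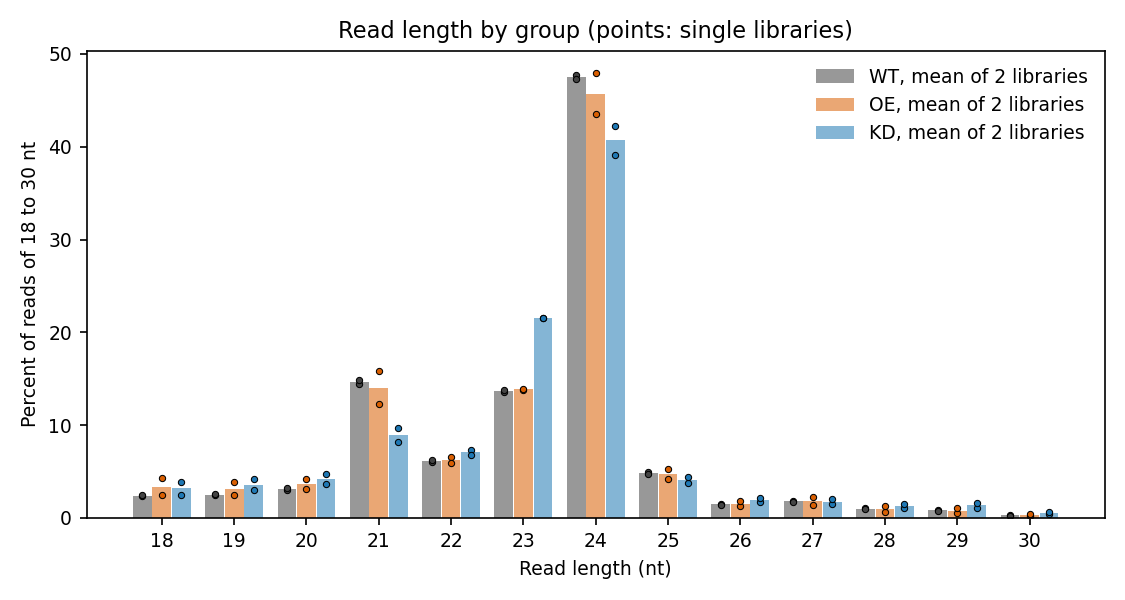
Share of each read length among reads of 18 to 30 nt in WT, OE and KD (bars, mean of 2 libraries; points, single libraries).

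**Figure D4:**
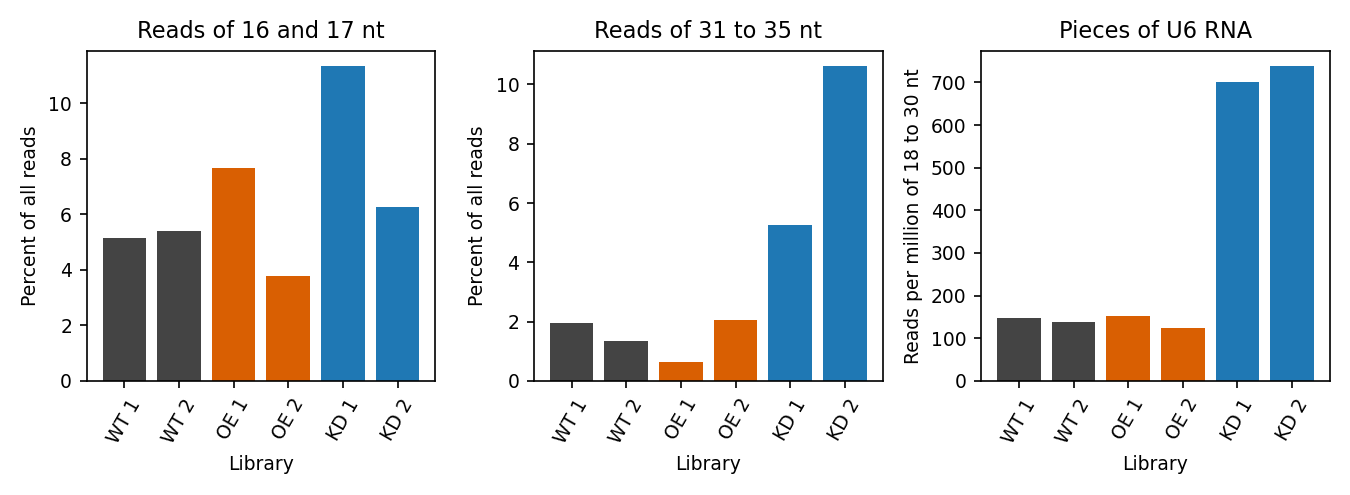
Reads of 16 and 17 nt, reads of 31 to 35 nt and exact pieces of U6 RNA in each library.

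Single sequences nearly absent from WT were abundant in KD. CGGATGTTTACGCAATGTGATTTC had no read in WT and 107 ± 6.62 rpm in KD, at least 414-fold higher at a floor of 3 reads per library. AGAAGGCAGCTACGTCTGAGCT rose from 0.432 ± 0.0175 to 355 ± 36.7 rpm, CAGGACTCGAGGAAGAAGCCCCG from 0.173 ± 0.00700 to 117 ± 17.7 rpm, GGTCAAGGAAGTTGGTGAACTGA from 0.215 ± 0.0524 to 69.6 ± 6.63 rpm and GCAGAGGTCCGAACCGACTGATG from 0.217 ± 0.0699 to 66.7 ± 4.69 rpm. In the other direction, ACACACACGAGAACTCGCGAGAAA had 87.6 ± 1.77 rpm in WT and no read in KD, at least 227-fold lower. ATGCACCCGGATACTGTAGAACAC fell in KD as in OE (WT over KD 507, 95% counting interval 173 to 2461, from 3 reads in KD), as did ATGCACCCGGATACTGTAGATCAC (2.77 ± 0.858 rpm). TCGGACCAGGCTTCATTACCC and TCGGACCATGCTTCATTCCCC, each 1 mismatch from miR166, fell from 80.9 ± 0.697 and 150.4 ± 7.01 rpm to 7.52 ± 0.0159 and 14.3 ± 2.53 rpm. The largest adjusted p among these 10 sequences was 3.1e-09 (TCGGACCATGCTTCATTCCCC).

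In KD against WT, 35502 of 96010 sequences passed by the edgeR quasi-likelihood test and 19288 by DESeq2. Of the 35502, 19862 were higher and 15640 lower (55.9% higher, against 43.8% with library totals and 69.5% by DESeq2). Among 23-nt sequences 5814 rose and 935 fell, among 21-nt sequences 1032 rose and 2845 fell, and among 24-nt sequences 5982 rose and 8300 fell.

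Set against each other, OE was above KD in miR530 (16 ± 4.22 against 0.836 ± 0.0791 rpm, 3.90 ± 0.45, adjusted p = 2.0e-12), miR166 (19457 ± 2999 against 2265 ± 233 rpm, 2.76 ± 0.30, adjusted p = 1.8e-13), miR159 (2.13) and miR399 (1.76) in every alternative run. miR1432 (2.36), miR529 (1.48), miR167 (1.21) and miR156 (1.16), against SPL factors in the cases of miR529 and miR156, were higher in OE, and so was miR444 (0.73, adjusted p = 0.040). With exact mature sequences these 5 calls ended (adjusted p = 0.12, 0.12, 0.91, 0.061 and 0.070), and the value of miR167 was 0.056. For miR529 the exact count kept 2 and 2 of 35708 and 27029 reads in KD, with a value of 1.70. It therefore tested almost none of that family. For miR167 it kept 87 and 63 of 948 and 735 reads in KD. miR395 (−3.26, from −6.38 without OE replicate 1 to −2.09 without OE replicate 2), miR172 (−1.41), miR2275 (−1.19, adjusted p = 8.8e-04), miR169 (−1.17), miR164 (−1.005) and miR827 (−0.87, adjusted p = 0.070 with exact mature sequences and 0.13 with library totals) were lower in OE than in KD. The difference in miR2118 (0.53, adjusted p = 0.14), miR162 (0.49, adjusted p = 0.15), miR168 (0.55, adjusted p = 0.12), tasiR-ARF (−0.64, adjusted p = 0.14), miR397 (0.53), miR390 (−0.21) and miR528 (0.09) did not pass. The signs of miR397, miR390 and miR528 were uncertain. Their values were −0.095 for miR397 without KD replicate 1, 0.14 for miR390 with library totals and −0.34 for miR528 with TMM from the families alone. With library totals miR2118, miR162 and miR168 passed (adjusted p = 0.0053, 0.0055 and 0.0028), with TMM from the families alone miR390 (−0.65, adjusted p = 0.010) and tasiR-ARF (−1.08, adjusted p = 0.014) passed, and in any register miR397 was higher in OE (2.53, adjusted p = 1.8e-11).

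In OE against KD, 15 of 34 families passed by the edgeR quasi-likelihood test, 9 higher and 6 lower in OE. TMM moved all values by −0.34 log2 against library totals, which gave 17 higher and 5 lower, and TMM from the families alone gave 10 higher and 14 lower. Without KD replicate 1 the calls of miR172, miR169, miR164 and miR827 ended (adjusted p = 0.11, 0.084, 0.087 and 0.19). Without KD replicate 2 those of miR2275, miR156 and miR444 ended (0.077, 0.069 and 0.26), and miR444 also without OE replicate 1 (0.24). The call of miR827 ended without OE replicate 2 (0.17), and that of miR395 without OE replicate 2, KD replicate 1 or KD replicate 2 (0.086, 0.054 and 0.11) and with a replicate block (0.052). With only the 2 groups compared miR827 and miR444 did not pass (0.12 and 0.15).

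As sets, conserved miRNAs were higher in OE than in KD (5 families higher and 5 lower of 21, set median 0.95, adjusted p = 1.3e-08, and 0.87 with an estimated correlation). Monocot miRNAs followed (4 higher of 10, set median 0.71, adjusted p = 0.0069, and 0.87 with an estimated correlation), a call that ended without OE replicate 1 or KD replicate 2 (adjusted p = 0.064 and 0.084) and with the minimum of 10 rpm (0.15). Copper miRNAs (0 of 4 families past the threshold by edgeR, adjusted p = 0.76), nutrient miRNAs (1 higher and 2 lower of 3, adjusted p = 0.26), the phasiRNA triggers (1 lower of 2, adjusted p = 0.75, median 0.10 and mean −0.00) and miR390 with tasiR-ARF (0 of 2, adjusted p = 0.65) did not pass. The counts over each list alone were the same.

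Reads of 23 nt were fewer in OE than in KD (−0.64 ± 0.04, adjusted p = 0.00017), the only 1 of 13 lengths to pass by the edgeR quasi-likelihood test, with 21 nt at 0.65 (adjusted p = 0.053). Without OE replicate 1, OE replicate 2 or KD replicate 1, 21 nt passed as well (adjusted p = 0.029, 0.0030 and 0.033), and 24 nt passed without OE replicate 1 (0.24, adjusted p = 0.015). Of the first-base classes 13 of 20 passed, 5 higher in OE (T21, 1.03; A21, 0.69; T22, 0.30; A24, 0.29; T24, 0.28) and 8 lower, led by G23 (−1.14), G20 (−1.01) and C23 (−0.998). The count of 13 was 8 without KD replicate 1 or KD replicate 2. Of the 5 higher classes T21 kept its call in every alternative run. A24 lost it in 6 (largest adjusted p 0.16, without KD replicate 1), A21 in 4 (0.11, without the 20 most abundant sequences), T22 in 2 (0.065, without KD replicate 2) and T24 in 2 (0.082, without KD replicate 1). Of the lower ones, G23 and C23 kept theirs, whereas G20 lost its call with distinct sequences (0.20), with only the 2 groups compared (0.093) and without OE replicate 2, KD replicate 1 or KD replicate 2 (0.066, 0.13 and 0.058). As sets, 11 classes passed at the preset correlation and 0 with an estimated correlation.

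Among single sequences, ACTTGCACTGTGGAGAACTCAAAT had 119.9 ± 2.75 rpm in OE and 2.31 ± 0.331 in KD, and ACACACACGAGAACTCGCGAGAAA 63.0 ± 6.33 rpm in OE and no read in KD (at least 163-fold higher in OE). TTCGGACCAGGCTTCATTCCC, a miR166 form that starts 1 base upstream, had 2954 ± 452 rpm in OE, 258 ± 13.3 in KD and 1216 ± 24 in WT. CGGACCAAGGAGTCTGACATGCG (89.3 ± 32.8 against 7.54 ± 1.47 rpm) and GAAACGGGACTTGAATTGTAGGCC (53.7 ± 1.93 against 4.76 ± 0.613 rpm) were higher in OE too. Sequences lower in OE than in KD were mostly longer, namely CTAAGCAGAGGTCCGAACCGACTGATG (0.587 ± 0.0583 against 109 ± 8.37 rpm), CCTTGGGCCGGGCCGGCCGGTCCGCCTC (1.09 ± 0.649 against 198 ± 40 rpm), GAACCCACAAAGGGTGTTGGTCGATTA (0.650 ± 0.147 against 85.2 ± 16 rpm), TGACAGGACTCGAGGAAGAAGCCCCGGC (0.587 ± 0.0583 against 76.1 ± 4.47 rpm) and the 21-nt GAAGGCAGCTACGTCTGAGCT (0.765 ± 0.696 against 90.6 ± 15 rpm). The largest adjusted p among them was 2.7e-08 (CGGACCAAGGAGTCTGACATGCG). In OE against KD 33379 sequences passed by the edgeR quasi-likelihood test, 14205 higher and 19174 lower (42.6% higher, against 60.7% with library totals and 28.4% by DESeq2), and 18182 by DESeq2.

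OE and KD shared more changes against WT than opposite ones, although the labels give opposite changes of AGO17. miR2118 and miR528 were lower in both in every alternative run, as were the sequences ATGCACCCGGATACTGTAGAACAC and ATGCACCCGGATACTGTAGATCAC. These sequences differ at 1 base only, so they need not be independent changes. Several other sequences named for OE also moved the same way in KD by their means, as given above. Of the sequences past the threshold in both, 2223 were higher in both and 3837 lower in both (86.4% in the same direction), and 350 and 603 moved in opposite directions. Both groups were compared with the same 2 WT libraries, and simulated unchanged groups sharing WT gave a correlation of the fold changes of 0.411 (observed 0.361) and a covariance of 0.158 (observed 0.844) over 10 simulations. A split of WT, added after the data were seen, gave OE and KD separate WT libraries. A state common to both WT libraries would still move OE and KD the same way, and the split cannot remove it. With OE against WT replicate 1 and KD against WT replicate 2, 491 sequences were higher in both, 1129 lower in both and 198 moved in opposite directions (correlation 0.314, covariance 0.820). With the WT libraries exchanged, the counts were 457, 1142 and 175 (correlation 0.309, covariance 0.812).

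Some sequences of 20 to 22 nt were absent from both WT libraries. In OE the most abundant was TACTCCGGCGGCGAATTGAGC at 16 ± 0.103 rpm, at least 61.8-fold higher than in WT at a floor of 3 reads per library. In KD they were AAGAAGGCAGCTACGTCTGAGC and AGAAGGCAGCTACGTCTGAGC at least 118-fold and 114-fold higher. These are forms of one sequence with different ends. With a T added at the 3' end, they occurred in both WT libraries (0.672 and 0.445 rpm, and 0.420 and 0.445 rpm). The origin of the sequences absent from WT, and whether any comes from the AGO17 gene or a transgene, was not tested here.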

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

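Some tests here were chosen only after the results had been seen. They were the count of U6 and 5.8S pieces, the odds ratios of shortened forms and the versions with mean shares. So were the versions without sequences dominated by their short form and the looser searches for variants. The test for noise of one library and the count of miR2118 pieces were chosen then too. The other tests in this part were set before theirs.

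Reads outside 18 to 30 nt entered no comparison of the report, apart from the pieces added to miR2118 below, and were more frequent in KD than in WT. Reads of 31 to 35 nt made up 7.939% of all KD reads (5.27% and 10.6%) against 1.65 ± 0.444% in WT. Reads of 16 and 17 nt made up 8.787% (11.3% and 6.25%) against 5.26 ± 0.174% in WT, and OE replicate 1 held 7.68%, more than KD replicate 2. Among the long reads, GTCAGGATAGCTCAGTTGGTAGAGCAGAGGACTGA came to 1025 rpm over all reads in WT, 295 in OE and 11849 in KD. These differences were not tested.

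The rise of 23-nt reads in KD, with fewer 24-nt reads, may come in part from loss of 3' ends as a general process. Among 16 miRNA families the share of reads lacking the last base was 2.467 times the WT share in the median (interval 1.70 to 3.78). The ratio was above 1 in 14 of 16, and its median was 1.14 in OE. The median shares were 1.55% in WT and 4.56% in KD. Such loss keeps the first base. A23 rose as A24 fell (0.50 and −0.46). G23 and C23 rose (1.16 and 1.04) with little change in G24 and C24 (−0.08 and 0.09). For 7110 abundant 24-nt sequences, loss of their own last base cannot be told apart from no loss by the test set beforehand, because the median ratio of 23-nt to 24-nt forms (2.319) and the pooled reads lacking the last base per 100 (19.9 and 18.5 in KD, 21.6 and 22.3 in WT) point in opposite directions. Versions chosen after that favour loss, with an odds ratio stratified by sequence of 1.81 (interval 1.70 to 1.92), mean shares of 8.99% in KD and 5.36% in WT, and, without the 133 sequences whose short form was the larger in WT, an odds ratio of 2.06. The interval for the miRNAs resamples families and that of the odds ratio resamples sequences, so neither covers the spread between libraries. By library, the stratified odds ratio was 1.88 in KD replicate 1 and 1.76 in KD replicate 2. Other loci may contribute as well. Over 5814 higher sequences, 31.69% of the rise came from the first 23 bases of a 24-nt sequence at least as abundant in WT. The remaining 68.3% came from others. These may include 24-nt sequences lacking their first base, or with a scarcer 24-nt form in WT, so they need not be other loci. The 5814 sequences rose by 17935 rpm, whereas all 23-nt reads went from 136523 to 215223 rpm, so most of the rise was not covered. First-base loss also rose (odds ratio 1.40) and U6 pieces were at 719.8 rpm in KD and 144 rpm in WT, so a difference in RNA integrity stays open, beside an effect of AGO17 or of developmental stage, neither of which was tested.

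Another pattern was 37 cases, in comparisons with WT, of a sequence at 50 rpm or more in one group and nearly absent from another. They include 1 sequence that was abundant in WT and counted against both OE and KD. Many of the cases in KD are forms of the same fragment with different ends. The 37 are therefore not independent, and the counts over them below include some fragments repeatedly. Allelic variants would leave a partner sequence with 1 changed base and the opposite change, and this held for 0% of the 37. The same search found such a partner for 0 of 836 unchanged sequences and for 0 of 2303 in a looser set. It was thus not shown able to find one. Of the 37, 4 had any 1-base variant at 5 rpm or more in the groups compared. This argues against a 1-base allele of that abundance for the others. Scarcer or more distant allelic variants stay open. Noise of one library is argued against, since the 37 were chosen by group means alone and 37 of 37 were within a factor of 2 in both libraries of their group. Of the 37, 32 were abundant in KD and nearly absent from WT. Pieces of U6 RNA were also higher in KD than in WT, and the 32 may include such pieces, which was not checked. A difference in RNA integrity or in the structural RNA retained, a locus present in some plants only, and regulation by AGO17 all remain possible. None of these was tested for the 37.

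The fall of miR2118 in OE and KD was weighed against scaling and shortening. The smallest fall over the scalings was −0.9922 (OE with TMM from the families alone, adjusted p = 0.0014 by edgeR). That is just short of the bound of 1 log2 unit set beforehand, so by that bound the test did not decide. The fall was still past the threshold under a scaling that reversed other families. By this reading, made only after the value was seen, scaling is unlikely to be the whole cause. Counting reads of 18 to 26 nt (−1.699 in the group with the smaller fall) tested nothing, since the pattern for miR2118 gained 1 read. Adding reads of 16 to 19 nt that are exact pieces of the counted sequences (7 and 8 in WT, 3 and 2 in OE, 5 and 4 in KD) left −1.696 ± 0.31 SE there, which argues against shortening to 16 to 19 nt, while shorter reads are not in the files. An effect on miR2118 of any change of AGO17, of transformation or of stage remains open, since both transgenic groups moved the same way.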

How the results depend on the processing

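TMM from 20 to 24 nt, family reads of 18 to 26 nt, miR397 in any register and the split of the WT libraries were chosen after the results had been seen, as was the narrowing to named lengths, classes and families; the other alternatives were set before. Over all alternatives 1521 values kept direction and side of the threshold, 130 lost their call, 28 gained one and 28 reversed. The named single sequences kept direction and call in every alternative that tested them. Unless stated, the cause of a change was not tested. With 2 libraries per group and 3 residual degrees of freedom, leaving out a library leaves 1 in its group, assumed to vary like the others. Genome windows and matches to the AGO17 gene were not run.

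With distinct sequences in place of reads, length 21, 22 and 23 in OE against WT turned to 0.10, −0.023 and −0.035 and class T23 in KD against WT to −0.016, and 2 lengths passed in OE against KD. Also 2 lengths passed there with library sizes of 20 to 24 nt, with DESeq2 and with a replicate block. Without the 20 most abundant sequences length 22 in OE turned to −0.012, and without sequences seen once class G22 in OE against KD to 0.16. DESeq2 called 1 first-base class in OE. With only the 2 groups compared, 17 classes passed in KD against WT and 7 in OE against KD. The replicate block, for which the numbers give no ground, called 17, 20 and 14 families and 14897, 36386 and 34068 sequences in OE, KD and OE against KD, and ended the calls of miR395 in OE against WT and OE against KD (adjusted p = 0.055 and 0.052).

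Families depended on the scaling. With library totals miR390 in OE against KD turned to 0.14. With TMM from the families alone, which sets their typical change near 0 by construction, miR399, miR394, miR396, miR168, miR2275, miR390 and tasiR-ARF in KD against WT turned to 0.10, 0.091, 0.12, 0.96, 0.85, 0.22 and 0.83, miR528 in OE against KD to −0.34, and 24 families passed in OE against KD. Exact mature sequences left 7 there, but changed no count of miR2118, miR2275 and tasiR-ARF, which were counted by pattern, and so tested nothing for them. With family reads of 18 to 26 nt miR528 in OE against KD turned to −0.034. With miR397 in any register its value in OE against WT turned to 1.27 (adjusted p = 1.9e-04). The main count held few of the reads counted that way, and whether the others are miR397 was not tested.

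For single sequences, DESeq2 called 3176, 19288 and 18182 in OE, KD and OE against KD. A minimum of 10 reads in sum gave 57662 in KD and 52170 in OE against KD from more sequences tested, and a minimum of 10 rpm gave 2279, 4300 and 4292, with 6655 tested. With an estimated correlation 0, 2 and 0 sets passed by camera, where the preset correlation gave 11, 18 and 13. The copper set in OE against KD turned to −0.66 with the minimum of 10 rpm, and that in KD against WT was −0.70 (adjusted p = 0.54). With OE against one WT library and KD against the other, 1620 and 1599 sequences moved the same way in both, against 6060 with shared WT libraries, with 2 residual degrees of freedom.

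Leaving out each library in turn gave 1 to 3 lengths in OE against KD and 1 to 2 in KD against WT, 8 to 14 first-base classes in OE against KD, 4 to 18 families in OE against WT, 10 to 18 in KD against WT and 10 to 20 in OE against KD, and 3216 to 10994 sequences in OE against WT. In OE against WT, length 21 ranged from −0.26 to 0.11 (higher without OE replicate 2), length 22 from −0.062 to 0.093 and length 24 from −0.13 to 0.014 (both reversed without OE replicate 1). In OE against KD, miR528 ranged from −0.16 to 0.36 (reversed without OE replicate 1 or KD replicate 1), miR390 from −0.50 to 0.16 (reversed without OE replicate 2 or KD replicate 1) and miR397 from −0.095 to 1.65 (reversed without KD replicate 1). The conserved and monocot sets in OE ranged from −0.50 to 0.020 and from −0.22 to 0.090, both reversed without OE replicate 2. As to depth, sequences near the floors of 0.252 to 0.390 rpm cannot be told from 0.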

Other observations

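The form of miR166 that starts 1 base upstream made up 6.38 ± 0.0369% of miR166 reads in WT, 15.5 ± 0.0133% in OE and 11.9 ± 0.608% in KD. For miR1425 the upstream form made up 11.1 ± 0.489%, 17.1 ± 2.46% and 10.3 ± 0.380%. Both were noticed in the data, and no test of the difference was run.

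The 16-nt GGGGACGTAGCTCATA came to 12822 rpm over all reads in WT, 3904 in OE and 29678 in KD. The 17-nt CAGGCTTTCTTGAACTG, the end of the miR396 sequence, came to 3686, 3958 and 786.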
